A study of Nitrosomonas europaea with 9 samples.

How the data were processed

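Cells of Nitrosomonas europaea were grown in 2 L chemostats at 30 °C and 600 rpm in medium with 30 mM ammonium sulfate, per the labels' protocols. RNA was depleted of rRNA and sequenced as paired reads of 100 nt, per the labels' protocols, and the column names put all libraries in the same sequencing lane. The samples fall into 3 groups of 3 biological replicates by the carbonate condition in their labels. The numbers in the sample titles name the replicates. The labels do not say whether equal numbers pair them across groups, and they were treated as unpaired.

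The authors deposited 1 table with 2620 genes. Its counts are total and unique gene reads per gene and library, per the file headers; total reads also hold reads that are not unique to 1 gene. RPKM values deposited beside them equal total reads divided by the gene's length and the library's total gene reads, rRNA included, within a relative tolerance of 1e-06. The table's p-value and signed fold change per comparison are the authors' own, from an EDGE test with a common dispersion per the file headers. They were used only to set beside the results computed here, with the p as deposited and after Benjamini-Hochberg adjustment where stated. The aligner, its settings and the genome build are not given in the sources used here. The authors' quantile-normalized values were not used here. Gene lengths outside rRNA and tRNA are all multiples of 3 (coding length). Positions count from 1.

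The table gives a symbol for 947 genes and only a locus tag for 1673. The files do not pair those tags with names, so at most 2 that rose and 2 that fell are printed. rRNA and tRNA, 45 genes, were left out before library sizes were computed, which left 2575. The remaining depth of 2000149 to 4198636 reads makes 3 reads equal to 0.715 to 1.50 CPM. Below 90% of reads unique to 1 gene (154 genes), a value was treated as uncertain between copies.

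Total gene reads were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, low counts removed by filterByExpr, a robust quasi-likelihood fit of all 9 libraries with group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors are the fold change divided by the square root of the test's F. Pooling the spread over groups matters here because replicates varied least at 1.0 mM. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 22 lists with 3 or more tested genes, then with an estimated correlation and with fry. The edgeR and camera tests, the gene lists, most of the alternatives and the rule for named genes were fixed before the data were examined. The lists cover ammonia oxidation, the RuBisCO operon, other Calvin cycle enzymes, nitrogen oxide metabolism, nitrogen assimilation, the TCA cycle, the respiratory chain, ATP synthase, ribosomal proteins, translation factors and tRNA synthetases, RNA polymerase and sigma factors, iron uptake, chaperones and heat shock proteases, oxidative stress defence, flagella and chemotaxis, type IV pili and secretion, storage compounds and polyphosphate, phosphate uptake, metal efflux and copper, DNA replication and cell division, transposases and phage, and amino acid and cofactor biosynthesis, with carbonic anhydrase and toxin-antitoxin genes as lists too small to test. They were written with product names, which the table does not hold, and were carried over to its symbols by hand; genes without a symbol could not enter most of them.

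Named genes were, per comparison, the 8 largest increases and 8 largest decreases with a symbol and the 2 of each with a locus tag only, among called genes with a mean of 20 counts or more and no overlap between the groups' libraries. The rule was written for products other than hypothetical ones and was read here as genes with a symbol. Each list added up to 4 called genes, or up to 2 with the smallest p where none was called, and amoA, amoB, amoC, hao, the RuBisCO subunits, nitrite reductase (aniA in the table) and nitric oxide reductase were always given. cbbR and the neighbours of mnxG were named after their values were seen.

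The test was tried on simulated data made from the real means and library sizes for the comparison of 0.2 mM with replete. In 2486 genes, with 50 changed at each size, it recovered 8% at a fold of 1.5, 58% at 2, 100% at 4 and 100% at 8, with 9 false calls. The simulated spread was pooled over the groups, where the biological coefficient of variation was 22.9%. Between the real 0.2 mM libraries it was 30.4%, so recovery there may be lower. Alternatives were DESeq2 1.42.0, other scalings and filters, unique reads, RPKM on the scales log2(RPKM + 1) and log2(RPKM + 0.1) with limma, a replicate block, the libraries of the compared groups only, and leaving out each library. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.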

Results

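Nitrosomonas europaea is a bacterium that gains its energy by oxidising ammonia to nitrite and builds its biomass from CO2. Messenger RNA was measured in steady-state chemostats that differed in how much inorganic carbon they received. The replete cultures were fed 2 mM sodium carbonate and aerated at 100 mL per minute, and the cultures limited in carbon were fed 1.0 mM or 0.2 mM carbonate and aerated at 50 mL per minute. The pH was held at 7.5, by adding carbonate in the replete cultures and sodium hydroxide in the limited ones. Each condition had 3 biological replicates, 9 libraries in all. Carbonate supply, aeration and the base used for pH control therefore changed together between the replete and the limited cultures, and these could not be told apart in any comparison with replete.

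The libraries held 12941327 to 17774283 reads counted to genes. Ribosomal RNA took 76.4% to 84.5% of them in spite of depletion, which left 2000149 to 4198636 reads on the other genes; levels are given as CPM, counts scaled to library size. The biological coefficient of variation between replicates was 23.6% in replete, 9.48% at 1.0 mM and 30.4% at 0.2 mM. The closest pair was 1.0 mM replicates 2 and 3, with a coefficient of variation of 0.0539 against 0.101 and 0.116 for the other pairs of that group. The column of 1.0 mM replicate 2 has rd added to the sample's name, whose meaning is not given in the sources used here; both libraries were kept as separate samples because the labels name them so. Replete replicate 3 and 0.2 mM replicate 1 lay apart from the other members of their groups on the second principal component, and 0.2 mM replicate 2 lay among the replete libraries on the first. The mRNA of the RuBisCO large subunit, rbcL, alone made up 0.627% to 1.44% of the reads outside rRNA and tRNA in replete, 8.31% to 9.93% at 1.0 mM and 6.65% to 9.14% at 0.2 mM.

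**Figure D1:**
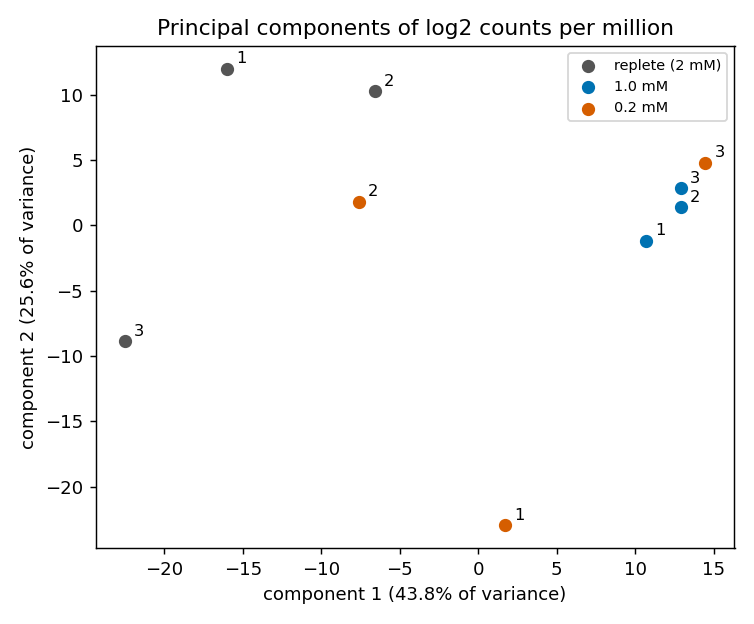
Each point is 1 library, placed by the first (horizontal, 43.8% of variance) and second (vertical, 25.6%) principal components of log2 CPM, coloured by condition and numbered by replicate. The 1.0 mM libraries lie close together, and the replete and 0.2 mM libraries are spread over both components.

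The comparison of 0.2 mM with replete asked which transcripts differed at the lowest carbonate feed. The genes of the RuBisCO operon, which encodes the CO2-fixing enzyme of the Calvin cycle, showed the largest increases among the genes with a symbol. cbbQ rose 14.1-fold (log2 3.82 ± 0.48, SE, n = 3 libraries per group) and cbbO 12.6-fold (log2 3.65 ± 0.46); both encode proteins known to activate RuBisCO. The small subunit gene cbbS rose 7.50-fold (log2 2.91 ± 0.28, adjusted p = 9.2e-04) and rbcL 7.46-fold (log2 2.90 ± 0.31, adjusted p = 0.00160). NE1917, at the end of the same run of genes, rose by 2.19 ± 0.32 on the log2 scale, and the chaperonin gene groES by 1.90 ± 0.39 (adjusted p = 0.0393). The regulator gene cbbR, next to rbcL, was at 1.34, which did not pass (adjusted p = 0.0920).

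Fewer named genes fell at 0.2 mM. NE2152 had the largest decrease, -3.62 ± 0.45 on the log2 scale, from a mean of 10877 CPM in replete to 882.1 CPM. The neighbouring trpE, which encodes a subunit of the first enzyme of tryptophan synthesis, fell by 1.19 (SE 0.18, adjusted p = 0.00583). moeZ fell by 1.20 (SE 0.20) and cobN, a subunit of a cobalt chelatase, by 0.90 (SE 0.16, adjusted p = 0.0169). In all, 29 of 2489 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 8 higher and 21 lower, and 28 of them changed by a fold of 2 or more. The replete and 0.2 mM libraries did not overlap for 347 genes, 13.9% of those tested, where chance gives 10%. DESeq2 called 84 genes, 38 higher and 46 lower, and without 0.2 mM replicate 2 edgeR called 137. In the authors' deposited table, 64 genes had a p under 0.05 and a fold of 2 or more, 28 higher and 36 lower. The fold changes of all 29 genes called here had the same sign there. That table rests on the same libraries, which favours the same sign. After Benjamini-Hochberg adjustment of the authors' p, 67 genes were under 0.05 at any fold.

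Of the 12 named genes called at 0.2 mM, 9 passed in each of the 9 refits that left out 1 library. groES did not pass without any 1 of the replete or 1.0 mM libraries (adjusted p = 0.236 without replete replicate 1). NE2541, which rose by 1.98 ± 0.38 from very low counts, was lost without any 1 of the replete libraries, 1.0 mM replicates 1 and 2, or 0.2 mM replicate 3 (adjusted p up to 0.108). cobN was lost without replete replicate 3, 1.0 mM replicate 2, or 0.2 mM replicates 1 and 3 (adjusted p up to 0.0621).

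**Figure D2:**
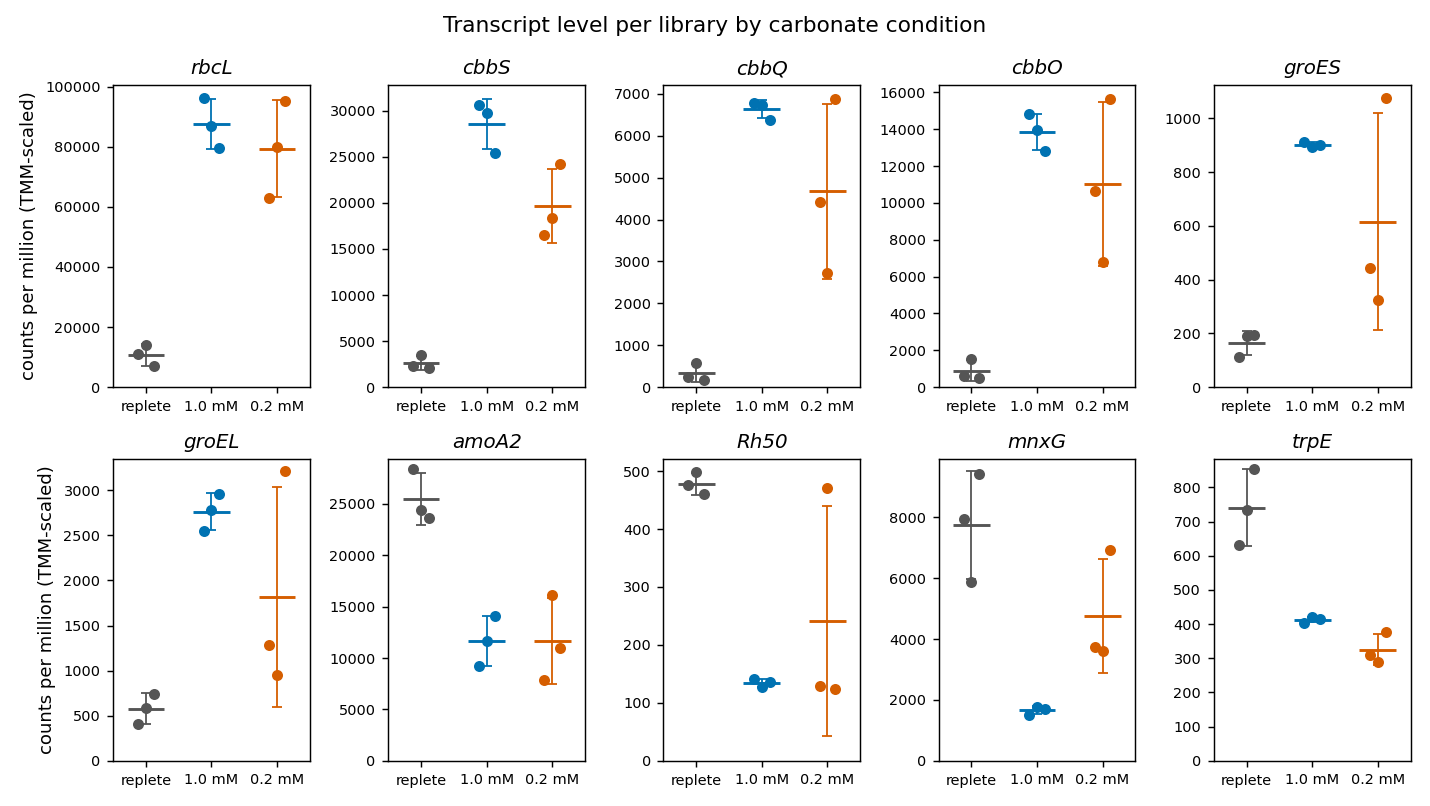
TMM-scaled CPM of 10 genes in each library, with the mean (line) and SD (bar) of the 3 libraries per condition. rbcL averaged 10646 CPM in replete, 87591 CPM at 1.0 mM and 79402 CPM at 0.2 mM.

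Taken by gene list, 4 of the 5 genes listed under the RuBisCO operon rose at 0.2 mM, and 5 of 5 when adjusted over the list alone. The fifth gene is the regulator gene cbbR, which lies beside the run from NE1917 to rbcL, and NE1917 is not in the list. The list stood above the other genes by camera (adjusted p = 3.4e-27; adjusted p = 0.0260 with an estimated correlation). Of the 15 ammonia oxidation genes none passed over all genes and 4 were lower when adjusted over the list alone. amoA1 and amoA2, which encode a subunit of ammonia monooxygenase, were at -1.13 ± 0.29 each (adjusted p = 0.101 and 0.104), amoB1 and amoB2 at -0.83 and -0.84, amoC1 at -0.51, amoC2 at -0.76, and amoC3 at 0.22. The hydroxylamine oxidoreductase genes hao1, hao2 and hao3 were at -0.13, -0.14 and -0.17, and hao1 was at 0.02 on the RPKM scale. As a list, ammonia oxidation was lower (camera adjusted p = 0.00101; adjusted p = 0.455 with an estimated correlation). The copies of amoA, amoB and hao have 0% of their reads unique to 1 copy, so their copies cannot be separated.

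The chaperones and heat shock proteases were higher as a list at 0.2 mM (adjusted p = 0.0218; adjusted p = 0.273 with an estimated correlation). Of its 16 genes groES rose, and 4 were higher when adjusted over the list alone; this call was lost without replete replicate 1 (adjusted p = 0.0613) and replete replicate 2 (adjusted p = 0.0950). The 33 translation factors and tRNA synthetases were also higher (adjusted p = 0.00825; adjusted p = 0.7496 with an estimated correlation). None of them passed over all genes and 1 was higher when adjusted over the list alone; cysS, which charges tRNA with cysteine, was at 0.87 ± 0.20 (adjusted p = 0.0771). The list was not called without 0.2 mM replicate 1 (adjusted p = 0.0611) or 0.2 mM replicate 3 (adjusted p = 0.199), nor without both libraries that stood apart (adjusted p = 0.115), and ammonia oxidation then had an adjusted p of 0.0505. Without 0.2 mM replicate 2, 8 lists were called, with amino acid and cofactor biosynthesis (adjusted p = 0.00121), ribosomal proteins and nitrogen assimilation (adjusted p = 0.0180 each) and DNA replication and cell division (adjusted p = 0.0206) added. Amino acid and cofactor biosynthesis also passed without replete replicate 2 (adjusted p = 0.00393), and the ribosomal proteins without 0.2 mM replicate 1 (adjusted p = 0.0133).

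The other lists did not pass at 0.2 mM, with these medians on the log2 scale and adjusted p from camera. The median was 0.18 over the 56 amino acid and cofactor biosynthesis genes (adjusted p = 0.0547), of which trpE fell, over all genes and when adjusted over the list alone; 0.17 over 53 ribosomal proteins (adjusted p = 0.293); 0.15 over 25 genes of DNA replication and cell division (adjusted p = 0.147); 0.34 over 9 other Calvin cycle enzymes (adjusted p = 0.303); and 0.31 over 8 ATP synthase genes (adjusted p = 0.408). It was 0.05 over 14 TCA cycle genes (adjusted p = 0.826), of which 1 was higher when adjusted over the list alone, 0.05 over 26 respiratory chain genes (adjusted p = 0.778), 0.22 over 4 phosphate uptake genes (adjusted p = 0.376) and 0.10 over 9 transposases and phage genes (adjusted p = 0.524). It was -0.14 over 37 flagella and chemotaxis genes (adjusted p = 0.303), -0.13 over 16 genes of metal efflux and copper (adjusted p = 0.484), -0.23 over 12 iron uptake genes (adjusted p = 0.368) and -0.23 over 6 genes of storage compounds and polyphosphate (adjusted p = 0.303). It was -0.08 over 4 nitrogen assimilation genes (adjusted p = 0.427), 0.03 over 10 genes of RNA polymerase and sigma factors (adjusted p = 0.303), and 0.08 over 3 nitrogen oxide genes (adjusted p = 0.778). In 7 genes of oxidative stress defence (adjusted p = 0.778) the median, 0.01, had the opposite sign to the mean, -0.04, and the test; in 15 genes of type IV pili and secretion (adjusted p = 0.848) the median was -0.01 and the mean 0.02, with the test's direction down and 1 gene lower when adjusted over the list alone. The nitrite reductase gene aniA was at 0.84 ± 0.90, with single libraries from 399.9 to 8737 CPM, and the nitric oxide reductase gene norB at -0.10 ± 0.23. The carbonic anhydrase gene cah was at -0.31 (adjusted p = 0.466); the toxin-antitoxin genes vapC and hipA were at -0.40 (adjusted p = 0.565) and -0.05 (adjusted p = 0.923).

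**Figure D3:**
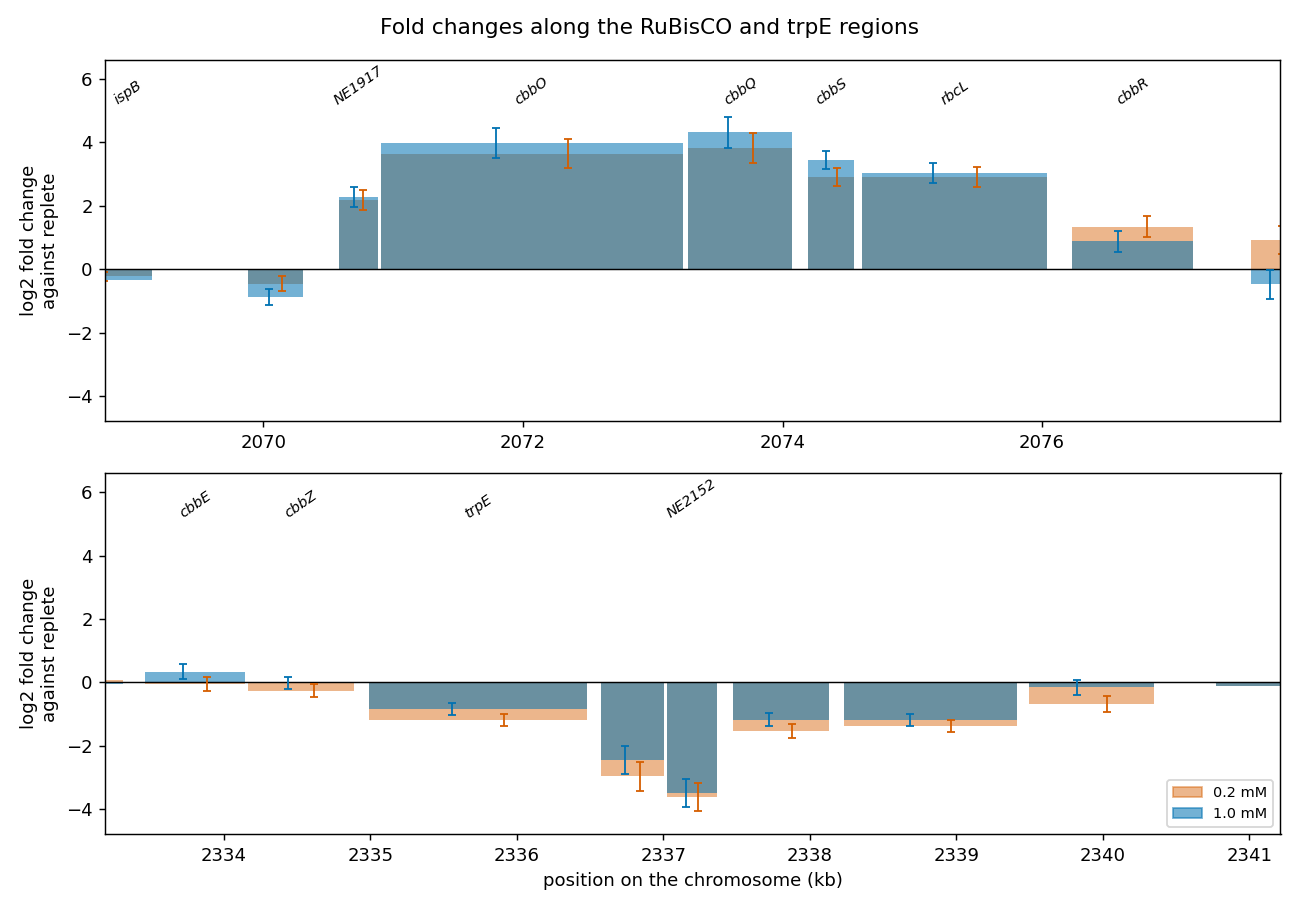
Log2 fold change against replete (bars, whiskers SE) along the RuBisCO region (upper) and the trpE region (lower), with position on the chromosome in kb. The run from NE1917 to rbcL spans positions 2070581 to 2076037 and the run that begins with trpE spans 2334991 to 2339414.

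The comparison of 1.0 mM with replete asked the same of the limited cultures with the higher carbonate feed. cbbQ rose 20.03-fold (log2 4.32 ± 0.49, n = 3 libraries per group), cbbO 15.8-fold, cbbS 10.9-fold (log2 3.44 ± 0.29, adjusted p = 2.0e-04) and rbcL 8.23-fold (log2 3.04 ± 0.32). The chaperonin genes groES and groEL rose by 2.45 ± 0.40 and 2.25 ± 0.41 on the log2 scale. NE2541 rose by 2.38 ± 0.37, NE1917 by 2.28 ± 0.32, the transcription termination factor gene rho by 1.39 ± 0.24, and gcvT, of the glycine cleavage system, by 1.43 ± 0.40 (adjusted p = 0.0496).

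Among the genes that fell at 1.0 mM, NE2152 was at -3.50 ± 0.44. mnxG, named for a multicopper oxidase, fell by 2.22 (SE 0.30, adjusted p = 0.00182), and Rh50, an ammonium channel of the Rhesus family, fell by 1.83 (SE 0.43, adjusted p = 0.0314). moeZ fell by 1.33, hemY by 1.16, ydiD by 1.12 and trpE by 0.84 (SE 0.18). amoA1 and amoA2 fell by 1.13 each (SE 0.29, adjusted p = 0.0406 and 0.0414), amoB1 by 1.07 and amoB2 by 1.08, and amoC2 by 1.18 (SE 0.32, adjusted p = 0.0487), while amoC1 was at -1.07 (adjusted p = 0.0598).

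In all, 195 of 2489 genes passed at 1.0 mM by edgeR, 88 higher and 107 lower, and 112 of them changed by a fold of 2 or more. The replete and 1.0 mM libraries did not overlap for 1028 genes, 41.3% of those tested, where chance gives 10%. The balance of directions depended on the scaling: total counts without TMM gave 126 higher and 69 lower, and RPKM gave 213 higher and 32 lower with a pseudocount of 1 and 209 higher and 31 lower with 0.1. RPKM, which is per total reads with rRNA, moved the median of all genes to 0.30 at 1.0 mM and 0.13 at 0.2 mM, against -0.02 and 0.01 with TMM. DESeq2 called 359 genes and the fit of the 6 libraries alone 492. In the authors' deposited table, 155 genes had a p under 0.05 and a fold of 2 or more, 62 higher and 93 lower. The fold changes of all 195 genes had the same sign there, which the shared libraries again favour. After Benjamini-Hochberg adjustment of the authors' p, 179 genes were under 0.05 at any fold.

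The count at 1.0 mM fell to 51 genes without replete replicate 1, 49 without replete replicate 3, and 38, 23 and 24 without 1.0 mM replicates 1, 2 and 3; it rose to 319 and 331 without 0.2 mM replicates 2 and 3. Of the 39 named genes called, 10 passed in each of the 9 refits: cbbQ, cbbO, cbbS, rbcL, groES, mnxG, moeZ, NE1917, NE2541 and NE2152. rho was lost without 1.0 mM replicate 2 (adjusted p = 0.0514), ydiD without any 1 of the 1.0 mM libraries (up to 0.0629), groEL without replete replicate 1 or 1.0 mM replicates 2 or 3 (up to 0.0679), and trpE without replete replicate 3 or any 1.0 mM library (up to 0.117). holC was lost without replete replicates 1 or 2 or any 1.0 mM library (up to 0.161). The other named genes, those of ammonia monooxygenase and Rh50 among them, were lost without replete replicate 1 or 3 or any 1.0 mM library, and amoA1, amoA2, nuoL and rplU also without replete replicate 2. The highest adjusted p in these refits was 0.164 for amoA2, 0.162 for amoB1, 0.185 for amoC2 and 0.132 for Rh50, each without 1.0 mM replicate 2; among the rest it ran from 0.0870 for icd to 0.178 for nqrD.

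By gene list at 1.0 mM, 4 of the 5 genes listed under the RuBisCO operon rose, and 5 when adjusted over the list alone (camera adjusted p = 1.0e-18, and 0.0671 with an estimated correlation). The fifth, cbbR, was at 0.88 (adjusted p = 0.115). Of 15 ammonia oxidation genes 5 fell, and 6 when adjusted over the list alone (adjusted p = 0.00882; adjusted p = 0.798 with an estimated correlation). The 5 were amoA1, amoA2, amoB1, amoB2 and amoC2. The copies of amoA, and those of amoB, hold the same reads, so they are not separate evidence. Camera at the preset correlation takes them as separate genes. hao1, hao2 and hao3 were at 0.11, 0.12 and 0.08, and amoC3 at 0.20. Of 16 chaperones and heat shock proteases 4 rose, groES, groEL, dnaJ (0.82 ± 0.18) and grpE (0.75 ± 0.18), and 5 when adjusted over the list alone (adjusted p = 0.0374; adjusted p = 0.414 with an estimated correlation). That list was lost without replete replicate 1 (adjusted p = 0.0706), replete replicate 2 (adjusted p = 0.140) and 1.0 mM replicate 1 (adjusted p = 0.05003).

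Genes of protein synthesis were higher as lists at 1.0 mM at camera's preset correlation only. The estimated correlation was 0.379 for translation factors and tRNA synthetases, 0.374 for ribosomal proteins and 0.240 for amino acid and cofactor biosynthesis. With it none of these lists passed, nor did they by fry (adjusted p = 0.176, 0.428 and 0.176). Of 33 translation factors and tRNA synthetases 3 rose, over all genes and when adjusted over the list alone: tuf2_1, an elongation factor with 25.2% of its reads unique (1.12 ± 0.26), serS (1.05 ± 0.22) and cysS (0.88 ± 0.20). The list had an adjusted p of 0.00882 (adjusted p = 0.827 with an estimated correlation). Of 53 ribosomal proteins rplU (1.02 ± 0.28) and rpmA (0.97 ± 0.20) rose, and 1 when adjusted over the list alone (adjusted p = 0.0166; adjusted p = 0.827 with an estimated correlation). The ribosomal list was lost without replete replicate 3 (adjusted p = 0.0760), without 1.0 mM replicate 1 (adjusted p = 0.05003), and without both libraries that stood apart (adjusted p = 0.0616). Of 56 amino acid and cofactor biosynthesis genes leuA1 (1.14 ± 0.31) and trpF (0.77 ± 0.17) rose and trpE fell; 9 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.00415; adjusted p = 0.827 with an estimated correlation).

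In the lists that did not pass at 1.0 mM, single genes of central metabolism changed. Of 14 TCA cycle genes icd, isocitrate dehydrogenase, rose by 1.15 ± 0.22 and fumC, a fumarase, by 0.70 ± 0.19; 2 were higher and 2 lower when adjusted over the list alone (list adjusted p = 0.855; median -0.09, mean 0.02, test up). Of 26 respiratory chain genes nuoL, of NADH dehydrogenase, rose by 0.90 ± 0.24, and nqrB and nqrD, of the sodium-pumping NADH reductase, fell by 0.88 and 0.67; 1 was higher and 3 lower when adjusted over the list alone (list adjusted p = 0.855, median 0.14). holC, of DNA polymerase, rose by 0.76 ± 0.19 among 25 genes of DNA replication and cell division (list adjusted p = 0.543, median 0.12), and pilJ fell by 0.77 (SE 0.15) among 15 of type IV pili and secretion (list adjusted p = 0.543, median -0.19), where 1 was lower when adjusted over the list alone. mnxG was the called gene among 16 of metal efflux and copper, with 2 lower when adjusted over the list alone (list adjusted p = 0.543; median 0.01, mean -0.16, test down), and Rh50 among 4 of nitrogen assimilation, with 1 lower when adjusted over the list alone (list adjusted p = 0.543, median -0.10).

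No gene passed at 1.0 mM in the remaining lists. The 9 other Calvin cycle enzymes had a median of 0.33 (list adjusted p = 0.0772), with the phosphoglycerate kinase gene pgk at 0.84 ± 0.26 (adjusted p = 0.0628); without replete replicate 2 this list passed (adjusted p = 0.0386). The median was 0.32 over 8 ATP synthase genes (adjusted p = 0.285), 0.01 over 10 of RNA polymerase and sigma factors (adjusted p = 0.699), where 1 was higher when adjusted over the list alone, -0.22 over 12 of iron uptake (adjusted p = 0.543), and -0.16 over 37 of flagella and chemotaxis (adjusted p = 0.517). It was -0.34 over 6 of storage compounds and polyphosphate (adjusted p = 0.245), -0.08 over 4 of phosphate uptake (adjusted p = 0.855), 0.01 over 9 of transposases and phage (adjusted p = 0.890) and 0.26 over 3 of nitrogen oxide metabolism (adjusted p = 0.855). Over 7 genes of oxidative stress defence it was 0.07 and the mean -0.01, with the test up (adjusted p = 0.971). aniA was at 0.84 ± 0.90, norB at -0.47 ± 0.23 (adjusted p = 0.214), cah at -0.62 ± 0.19 (adjusted p = 0.0612), vapC at -0.12 (adjusted p = 0.814) and hipA at 0.05 (adjusted p = 0.879).

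**Figure D4:**
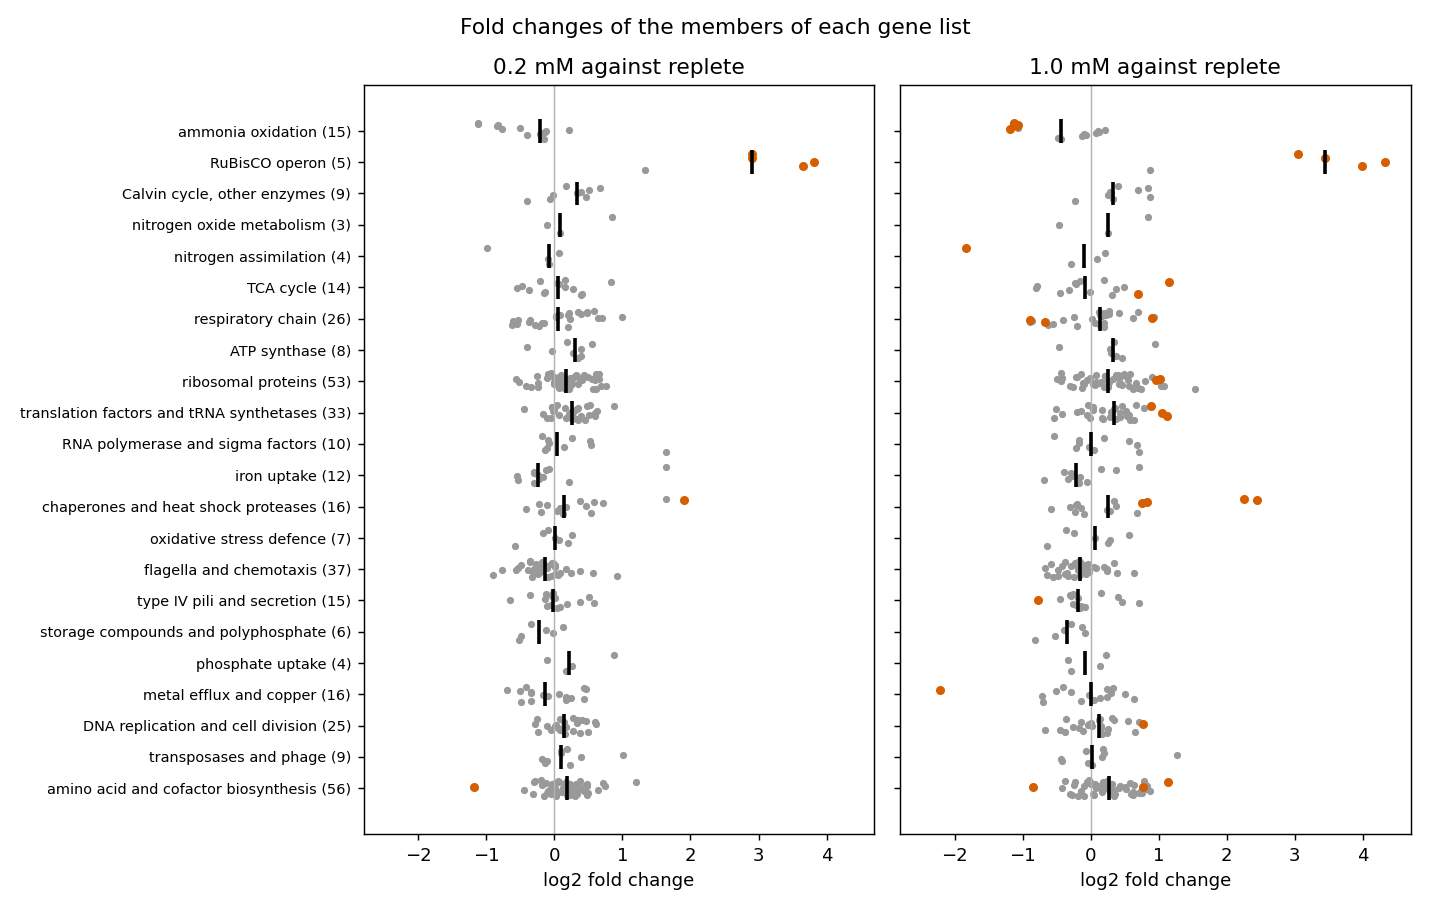
Log2 fold change against replete of each tested gene (points) in 22 gene lists, with the list's median (black bar) and its number of genes; orange points passed the test. The RuBisCO operon has a median of 2.91 at 0.2 mM and 3.44 at 1.0 mM.

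The comparison of 0.2 mM with 1.0 mM, both at the same aeration, asked whether the transcripts differed between the limited conditions. The gene nearest to passing was mnxG, 1.52 ± 0.29 on the log2 scale (n = 3 libraries per group, adjusted p = 0.634), with means of 4761 CPM at 0.2 mM and 1664 CPM at 1.0 mM. cbbS was at -0.54 ± 0.26 and Rh50 at 0.84 ± 0.42 (adjusted p = 0.808 each). edgeR called 0 of 2489 genes, with 139 at an unadjusted p under 0.05, while DESeq2 called 3, all higher at 0.2 mM: mnxG and the genes on either side of it, between positions 342677 and 350209. The libraries did not overlap for 277 genes, 11.1% of those tested, where chance gives 10%. In the authors' deposited table, 32 genes had a p under 0.05 and a fold of 2 or more, 23 higher and 9 lower at 0.2 mM. After Benjamini-Hochberg adjustment of the authors' p, 31 genes were under 0.05 at any fold, against the 0 called here by edgeR.

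As lists, amino acid and cofactor biosynthesis (median -0.09) and the ribosomal proteins (median -0.08) were lower at 0.2 mM than at 1.0 mM (adjusted p = 0.0485 each; adjusted p = 0.975 with an estimated correlation for both). Both were lost without replete replicate 1 (adjusted p = 0.0562 each), 1.0 mM replicate 1 (0.134 and 0.334), 1.0 mM replicate 2 (0.0650 each) and 0.2 mM replicate 2 (0.992 each), and the ribosomal list also without 0.2 mM replicate 1 (0.807). mnxG was the only gene of these 22 lists that passed when adjusted over the list alone. The RuBisCO operon (median -0.33, adjusted p = 0.558) and ammonia oxidation (median 0.01, adjusted p = 0.990) did not pass, and the other lists had adjusted p from 0.139, for phosphate uptake, to 0.990; ATP synthase passed without 0.2 mM replicate 3 (adjusted p = 0.0274). Median and mean had opposite signs in the TCA cycle (-0.04 and 0.01, test down), flagella and chemotaxis (-0.07 and 0.02, test down), nitrogen oxide metabolism (-0.00 and 0.06), metal efflux and copper (-0.00 and 0.07) and chaperones (0.00 and -0.04), and the test for iron uptake was down with a median of 0.01 and a mean of 0.04.

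Of the genes called at 0.2 mM, 27 were called at 1.0 mM too, 8 higher and 19 lower in both, and 0 were called in opposite directions. These included cbbQ, cbbO, cbbS, rbcL, groES, moeZ, trpE and cobN. Independent lists of these sizes would share 0.283 higher and 0.903 lower genes, a value that takes no account of the shared replete libraries. The log2 fold changes of the comparisons had a correlation across genes of 0.815, against a median of 0.506 in 50 simulations of unchanged groups. Their covariance was 0.215 against 0.0440, a difference of 0.172. The simulations drew every library anew, replete included, with independent genes and the same spread in each group. The real groups differed in spread (biological coefficient of variation 23.6% in replete, 9.48% at 1.0 mM and 30.4% at 0.2 mM). The simulated values are therefore idealized, and how far unequal spread would move them was not tested. Genes are not independent replicates, and with 3 replete libraries the controls could not be split, so part of the excess may come from the shared controls. The fold changes of the comparisons had the same sign for 80.7% of all genes, against a median of 66.6% in the simulations. For the genes called at 1.0 mM it was 195 of 195, but these were chosen for passing against the same replete libraries, which favours the same sign. DESeq2 called 77 in both, 34 higher and 43 lower, RPKM 17 (7 higher, 10 lower) with a pseudocount of 1 and 14 (6 higher, 8 lower) with 0.1. The count was 16 and 17 without 1.0 mM replicates 2 and 3 and 109 without 0.2 mM replicate 2.

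**Figure D5:**
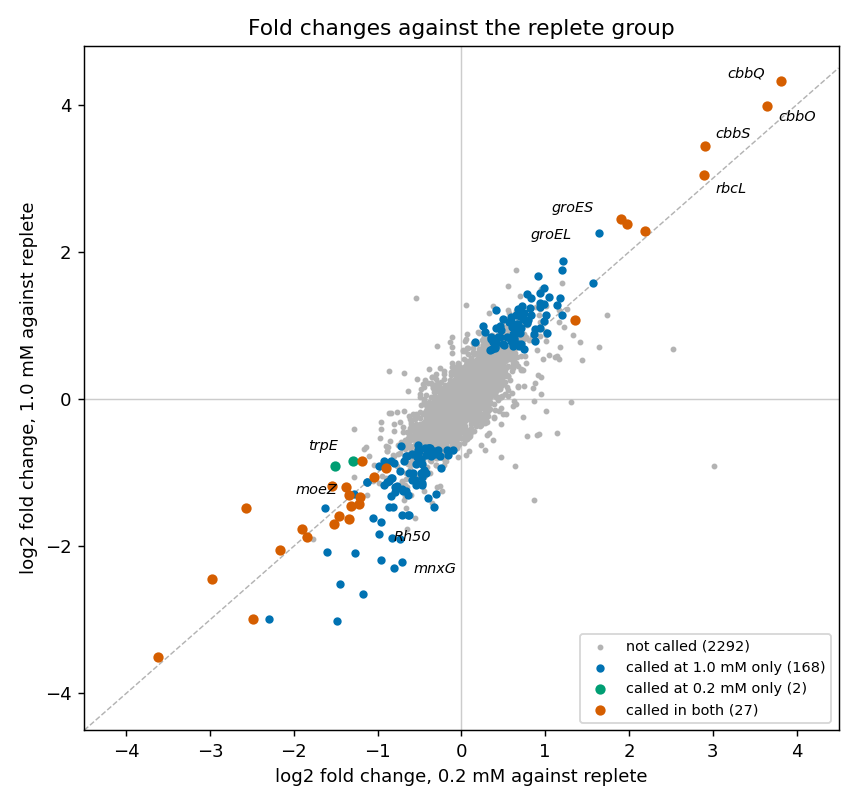
Log2 fold change of each gene at 0.2 mM (horizontal) and 1.0 mM (vertical) against the same replete libraries, with the line of equal change dashed. The 27 genes called in both comparisons (orange) lie in the lower left and upper right, and 168 were called at 1.0 mM only (blue).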

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

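The fits with a spread per group and without both replete replicate 3 and 0.2 mM replicate 1 were chosen after the results were seen. For 0.2 mM against replete, the 29 genes became 84 with DESeq2, 18 in the fit of the 6 libraries alone, 19 and 16 on the RPKM scale with pseudocounts of 1 and 0.1, 16 without both libraries, and 20 to 137 leaving out 1 library. For 1.0 mM the 195 genes became 112 at a fold of 2 or more, 359 with DESeq2, 492 in the fit of the 6 libraries alone, 505 with a spread per group, and 23 to 331 leaving out 1 library. Between 0.2 mM and 1.0 mM the 0 genes became 3 with DESeq2, 1 without both libraries, and 0 to 0 leaving out 1 library. The 27 genes called in both became 77 with DESeq2, 17 and 14 on the RPKM scale, 16 without both libraries, and 16 to 109 leaving out 1 library. RLE factors, no TMM, other low-count filters, unique reads and rRNA kept left these counts within 1.5 times. A similar count need not hold the same genes. At 1.0 mM, total counts without TMM again called 195, of which 157 were among the main calls. The RPKM scales called 245 and 240 at 1.0 mM, with 120 and 119 among the main calls.

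Of the gene lists, the 4 called at 0.2 mM became 1 with an estimated correlation, 1 with fry, 2 without both libraries, and 3 to 8 leaving out 1 library. The 6 at 1.0 mM became 0 with an estimated correlation, 2 with fry, and 4 to 6 leaving out 1 library. The 2 between 0.2 mM and 1.0 mM became 0 with an estimated correlation, 0 with fry, 1 without both libraries, and 0 to 3 leaving out 1 library. A fold threshold can only lower a count; for the other changes the cause was not tested.

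With the replicate number as a block, 20 genes were called at 0.2 mM, 42 at 1.0 mM, 0 between 0.2 mM and 1.0 mM, 18 in both, and 4, 6 and 1 lists. Libraries of the same number had correlations of -0.545 to 0.106 in their deviations from the group means, with 2 of 9 pairs above 0.1. These values show no clear effect common to equal numbers, but with so few libraries they cannot exclude a pairing.

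For the named genes, 1251 of 1524 alternative values kept the result, 247 were weaker, 17 were stronger and 9 changed sign, none of them for a called gene. Leaving out 1 library, amoC3 ran from -0.0161 (without replete replicate 2; -0.00 without 0.2 mM replicate 2) to 0.497 at 0.2 mM and from -0.0280 (without replete replicate 2) to 0.486 at 1.0 mM. hao1 ran from -0.213 to 0.0129 (without replete replicate 2) at 0.2 mM and was at 0.0170 and 0.0171 on the RPKM scales. norB ran from -0.277 to 0.14 (without 0.2 mM replicate 3) at 0.2 mM. aniA kept its sign at 0.2 mM but ran from 0.0486 to 2.52. hao3 ran from -0.00258 (without replete replicate 3) to 0.206 at 1.0 mM and was at -0.00239 without both libraries.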

Other observations

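All tests in this part except those of spread, sequencing depth and other splits of the libraries were chosen after the result they bear on was seen. Called genes lay next to each other on the chromosome. At 0.2 mM, 14 adjacent pairs were called in the same direction, against a mean of 0.179 and a highest value of 3 in 10000 random shuffles of the calls (permutation p = 1e-04, the smallest they can give). At 1.0 mM there were 49 pairs, against a mean of 7.48 and a highest of 20 (permutation p = 1e-04, again the smallest). The shuffles treat neighbouring genes as independent, so these p do not measure the spread between cultures. Besides the RuBisCO and trpE runs, 4 genes after cysG between positions 571180 and 576838 were lower at 0.2 mM (median -1.33), and 5 from the same start were lower at 1.0 mM (median -1.42). At 1.0 mM the run of groES and groEL spans positions 34605 to 37457, that of mnxG and its neighbours 342677 to 350209, that of rpmA and rplU 1412522 to 1414596, and that of amoB2, amoA2 and amoC2 2238597 to 2241670. fadE1, ydiD and 1 gene beside them between 2550138 and 2554902 were lower (median -1.09), and 4 genes ending with pth between 1968379 and 1972255 were higher (median 1.18).

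More genes were called at 1.0 mM (195) than at 0.2 mM (29). The gap closed or narrowed without 1.0 mM replicate 1 (38 and 25), 1.0 mM replicate 2 (23 and 23) or 1.0 mM replicate 3 (24 and 26), without replete replicates 1 (51 and 20) or 3 (49 and 22), and in ratio without 0.2 mM replicate 2 (319 and 137). In ratio it also narrowed with the replicate number as a block (42 and 20), with DESeq2 (359 and 84) and at a fold of 2 or more (112 and 28). It was wider without replete replicate 2 (224 and 28) and 0.2 mM replicates 1 (265 and 22) or 3 (331 and 28), and without both libraries that stood apart (166 and 16). It was wider too in fits of the 6 libraries alone (492 and 18), with a spread per group (505 and 21) and on the RPKM scales (245 and 19, 240 and 16). Other low-count filters, RLE factors, no TMM, unique reads and rRNA kept gave 185 to 212 genes at 1.0 mM and 25 to 32 at 0.2 mM.

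Sequencing depth is argued against as the source of this gap in the full set: with all libraries thinned to the same depth, the lowest ratio of calls over 10 thinnings was 5.54. The main fit shares the spread of each gene over all groups, and the median SE was 0.233 in both comparisons with replete. This argues against wider errors at 0.2 mM as the source of the gap in that fit. Whether a larger spread between the 0.2 mM libraries acted through the estimated fold changes stays open. The median ratio of fold changes, 0.2 mM over 1.0 mM, was 0.655 over genes chosen for passing at 1.0 mM, which favours a ratio under 1. Its 95% bounds, 0.623 and 0.716, come from resampling genes that share the same libraries. They do not measure the spread between cultures. A larger response at 1.0 mM stays open too: 1 of the 195 genes, mnxG, passed between the limited conditions when adjusted over those genes (adjusted p = 0.0496), but they were chosen with the same 1.0 mM libraries, which favours a difference, and over all genes its adjusted p was 0.634. These explanations cannot be told apart with 3 libraries per group.

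amoA and amoB were lower at 1.0 mM than in replete. A shift of reads between the copies of a gene is argued against as the cause, since the sum over both copies fell. Summed amoA was at -1.13 ± 0.29 (adjusted p = 0.0421), and summed amoB had an adjusted p of 0.0421 and amoC of 0.0567. The single copies of amoA and amoB had moved alike, so their sums had to give the same fold and add no separate support. Reads taken up by the RuBisCO operon are argued against as the whole cause: on total counts without TMM, where the operon's share moves every other gene, leaving it out took summed amoA from -1.03 ± 0.29 (adjusted p = 0.0473) to -0.84 ± 0.28 (adjusted p = 0.0564), and to -0.86 ± 0.28 (adjusted p = 0.0592) with tmRNA left out as well. That call ended as the fold moved toward 0 together with the median of all genes, from 0.08 to 0.28 and 0.26, so its loss restates the scaling. With TMM, leaving out the operon gave summed amoA at -1.12 ± 0.29 and amoB at -1.07 ± 0.27 (adjusted p = 0.0428 each). With tmRNA left out as well they were at -1.14 ± 0.28 (adjusted p = 0.0374) and -1.08 ± 0.26 (adjusted p = 0.0360). TMM trims the most extreme fold changes, so leaving out the operon could hardly move its factors. The values with TMM therefore add no separate support. Reads taken up by the operon would move the other genes alike. Without TMM and without the operon, summed amoA stayed at -0.84 while the median of all genes was 0.28. Whether carbon supply, aeration or pH control lowered amoA was not tested, as the design changed them together.

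At the genes called at 1.0 mM, the second 0.2 mM library lay nearest the replete mean of the 0.2 mM libraries in 131 of 195 genes, against 39 and 25 for the others; it was singled out for its place among the replete libraries on the first principal component, so these counts have no value by chance to be set against. Rh50 was at 471.1 CPM in it and at 129.5 and 124.2 CPM in the others. An exchange with a replete library is argued against, since rbcL, cbbS, cbbQ and cbbO lay at 4.43 times the highest replete library or more. RNA of a replete culture mixed in stays open, as what this culture held unmixed is not known and the other 0.2 mM libraries differ widely. From 0 at the replete mean to 1 at the mean of those libraries, Rh50 lay at 0.0194 and rbcL at 1.01. A single share of replete RNA in a culture like those would not give this. cbbS lay at 0.887, cbbQ at 0.449 and cbbO at 0.483. The genes called only at 1.0 mM had a median of 0.487 (95% bounds 0.410 and 0.582, from resampling genes and not libraries). The 2 tests tried, both set with the positions in view, decide nothing: the median of the 4 RuBisCO genes, 0.685, was chosen knowing that it would leave the question open, and an earlier form, rbcL against the highest limited library (0.811; cbbS 0.563, cbbQ 0.365, cbbO 0.401), argued against mixing with a median from the other scale.

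With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. The real split called 29 genes at 0.2 mM and the highest other 12 (1 split of 10 as large), 195 at 1.0 mM and the highest other 0 (1 of 10), and 0 between 0.2 mM and 1.0 mM with the highest other 0 (10 of 10).

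Across the 9 libraries, the deviation of the RuBisCO operon from its group mean was set against that of 21 other lists, with 216 permutations within groups (smallest p 0.00463). None passed after adjustment over the 21 relations. The 6 with a permutation p under 0.05 for r are given. Pearson's r was 0.967 (rho 0.817) with ATP synthase (permutation p = 0.0278 for r and 0.0556 for rho, adjusted p = 0.117), and 0.934 without the 2 libraries farthest from the median. It was -0.658 (rho -0.833) with iron uptake (permutation p = 0.00463 for both, adjusted p = 0.0648) and -0.228 without those 2 libraries, 0.842 with ribosomal proteins (permutation p = 0.00926, adjusted p = 0.0648) and 0.715 without them, and 0.932 with other Calvin cycle enzymes (permutation p = 0.0185, adjusted p = 0.0972) and 0.934 without them. It was -0.935 (rho -0.917) with flagella and chemotaxis (permutation p = 0.00926 and 0.0185, adjusted p = 0.0648), and -0.914 without those 2 libraries. It was -0.793 with metal efflux and copper (permutation p = 0.0463, adjusted p = 0.162), and -0.863 without them. The relation with ATP synthase had an r of 0.962 after a trend with gene length was removed, and the RuBisCO deviations had an r of -0.199 (rho -0.267, permutation p = 0.685 for r; 0.649 without those 2 libraries) with the share of rRNA. These were computed as explanations of the ATP synthase relation. They were set aside after their values were seen, and the rule for reading the rRNA value had been altered after it was seen, so no verdict is drawn from them.

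Without replete replicate 3 and 0.2 mM replicate 1, 1 gene known by a locus tag only was higher at 0.2 mM than at 1.0 mM (log2 2.74, adjusted p = 0.0471).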
